A study of Homo sapiens with 18 samples.

How the data were processed

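RNA was measured in 18 human libraries, 3 for each of 6 groups: second heart field derived fibroblasts (SHF-FB), cardiomyocytes (CM) and epicardium derived fibroblasts (EpiC-FB) of the H9 line, and primary fetal cardiac (fCFB), adult cardiac (aCFB) and dermal fibroblasts (dFB). Per the labels, the H9 libraries are independent differentiations and the primary libraries are technical replicates, so no test of a primary group holds spread between donors. The labels give the passage of the primary cells as 3 to 5 in one place and 1 to 5 in another. Libraries were stranded and enriched for poly(A) RNA per the labels. Per the submitters' processing notes, STAR 2.7.5b and featureCounts 1.6.4 were used with genome build hg38, and the notes give no strand setting, annotation or filter. Transcripts that overlap a gene on the other strand, and close paralogs, are therefore uncertain.

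The authors deposited raw read counts per Entrez gene for each library, with no normalization, and the values are whole numbers. The deposited TPM values were scaled by the authors to gene length and to the same sum in every library, and each library's ratio of counts to TPM was checked against every other library's. Among 10848 genes with at least 50 counts in every library, that ratio varied by a coefficient of variation of 0% after rounding. The count table held 28395 genes and 1 line with totals, and 27745 gene identifiers matched the RefSeq gene table, from which coordinates were taken. Before any test 111 genes (XIST, TSIX and genes on chromosome Y) were removed. Total counts per library ranged from 62535314 to 88060496. A check of donor-linked transcripts found that 1 of 18 libraries differed from the rest of its group. That library was kept in its group.

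Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, robust, TMM factors, filterByExpr with a minimum count of 10) under R 4.3.3, with only the compared groups in each fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a fitted log2 fold change of at least 1 in size. The standard error is the fold change divided by the square root of F. The comparisons were EpiC-FB against SHF-FB, their mean (hPSC-CF) against CM, against primary cardiac fibroblasts (the mean of fCFB and aCFB) and against dFB, aCFB against fCFB, and primary cardiac fibroblasts against dFB. Each H9 fibroblast group was also compared with fCFB and aCFB. Biological coefficients of variation were 0.588 for EpiC-FB against SHF-FB, 0.555 for hPSC-CF against CM, 0.442 for hPSC-CF against primary cardiac, 0.502 for hPSC-CF against dFB, 0.0883 for aCFB against fCFB and 0.0909 for primary cardiac against dFB. Levels are CPM with TMM factors over 18 libraries, and log2 CPM used a prior count of 2. For a gene without counts on one side the fold is a bound against 3 counts over that side. With 1 to 3 counts the ratio of counts is given with its 95% Poisson interval.

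Gene lists, 31 with 609 genes, were written from general knowledge before the data were examined and tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Lists with under 5 tested members were not set-tested. Camera with an estimated correlation and the fry test were run beside it. Set sizes of 200 genes, from primary cell comparisons, were tested in EpiC-FB against SHF-FB, with no library left out. Distances between a library and a group mean were root mean square differences of log2 CPM over 19181 genes.

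Named genes followed a rule written before the data were examined. Among called genes whose libraries did not overlap between sides, the rule takes the 4 per direction with the largest fold, at 10 CPM or more on the higher side and 10 counts or more on the lower. It adds the 2 per direction with the highest CPM among genes with at most 3 counts on the lower side. It also adds up to 2 members per direction of each described list, and a fixed panel of markers taken whatever they showed. The text gives a part of the genes so taken, and not every panel marker appears in it. Genes outside the rule are said to be so where they appear.

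Alternatives chosen before the data were examined were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no low-count filter, voom with a quality weight per group, all 18 libraries in one fit, no fold minimum, limma on log2(TPM + 1), and leaving out each library in turn. Leaving out SHF-FB 1 and 2 together, and using EpiC-FB alone in place of the hPSC-CF mean, were chosen after the data were seen. Where an omission left 1 library in a group, that library was assumed to vary like the others.

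The tests were also tested on simulated data with 200 genes changed and the spread of each comparison. At a log2 change of 1.5 and 3, edgeR recovered 0% and 46% of the genes in EpiC-FB against SHF-FB. There 5 of 51 calls were false. The recovered shares were 15% and 69% for hPSC-CF against CM (1 of 85 calls false). For hPSC-CF they were 73% and 95% against primary cardiac (4 of 172 false) and 24% and 82% against dFB (5 of 111 false). They were 99% and 98% for aCFB against fCFB (0 of 197 false). For primary cardiac against dFB both were 100% (1 of 201 false). Genes were drawn independently of each other, so the shared pattern that separates SHF-FB 1 and 2 from SHF-FB 3 was not simulated.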

Results

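Poly(A) RNA was measured in 18 human libraries that fell into 6 groups of 3. Per the labels, groups derived from H9, a human embryonic stem cell line, were cardiomyocytes (CM) and cardiac fibroblasts. The fibroblasts were made through an epicardial route (EpiC-FB) or a second heart field route (SHF-FB). The labels call these libraries independent differentiations, with the fibroblasts taken at passage 1. The other groups were primary human fibroblasts from fetal heart (fCFB), adult heart (aCFB) and skin (dFB), which the labels call technical replicates. P-values for the primary groups therefore measure only the spread between technical replicates, and no spread between donors entered any test. Total gene counts ranged from 62535314 in SHF-FB 1 to 88060496 in dFB 16, and mitochondrial genes took 2.33% to 7.37% of counts. Levels are given as CPM after TMM scaling, with the SD over the 3 libraries of a group, and log2 fold changes with their standard error (SE). A gene was called at an adjusted p under 0.05 with at least a 2-fold change.

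Libraries of the same group resembled each other except in SHF-FB. Correlations of log2 CPM across genes, which are not independent replicates, were at least 0.992 between libraries within fCFB, aCFB and dFB, at least 0.978 within EpiC-FB and at least 0.956 within CM. SHF-FB 1 and SHF-FB 2 correlated at 0.99 with each other but at only 0.822 and 0.825 with SHF-FB 3, whose closest library was fCFB 11 at 0.933. Transcripts of pluripotency and neural development genes separated the same libraries. The following genes were chosen after their values were seen. SOX2 stood at 182 and 173.5 CPM, OTX2 at 126.4 and 162.5 CPM, and LIN28A at 1091 and 1096 CPM in SHF-FB 1 and SHF-FB 2, and all 3 genes had 0 CPM in SHF-FB 3. COL1A1, the main chain of type I collagen, stood at 28.68 and 32.77 CPM in SHF-FB 1 and SHF-FB 2 against 2548 CPM in SHF-FB 3. The median of the 21 fibroblast identity genes was 24.2, 13.1 and 145 CPM in SHF-FB 1, 2 and 3. It was 670 CPM or more in each EpiC-FB library and 318 CPM or more in each primary library. In the CM libraries it was 118 to 131 CPM, above SHF-FB 1 and 2.

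**Figure D1:**
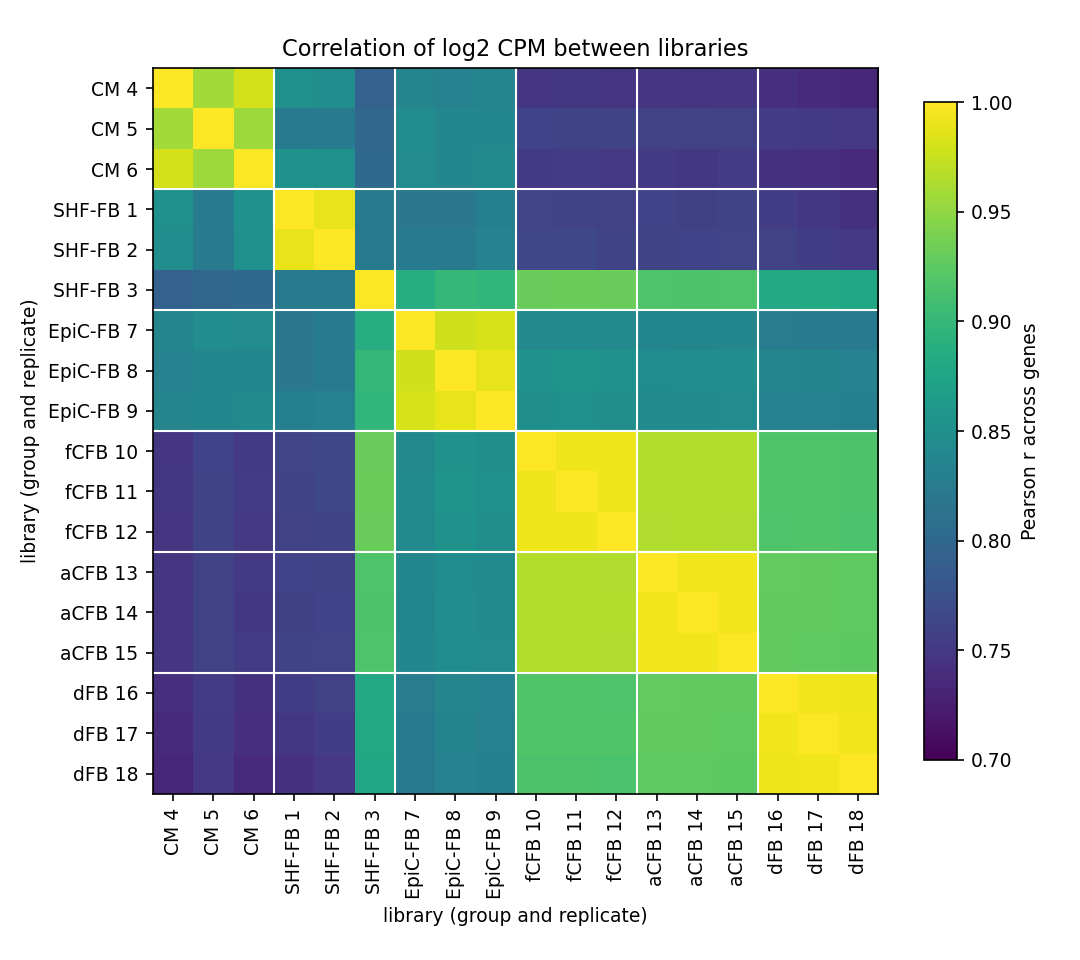
Pearson correlation of log2 CPM across genes between every pair of the 18 libraries; both axes list the libraries by group and replicate, and the colour scale runs from 0.7 to 1. SHF-FB 3 lies apart from SHF-FB 1 and 2 (0.822 and 0.825) and reaches 0.933 with fCFB 11.

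**Figure D2:**
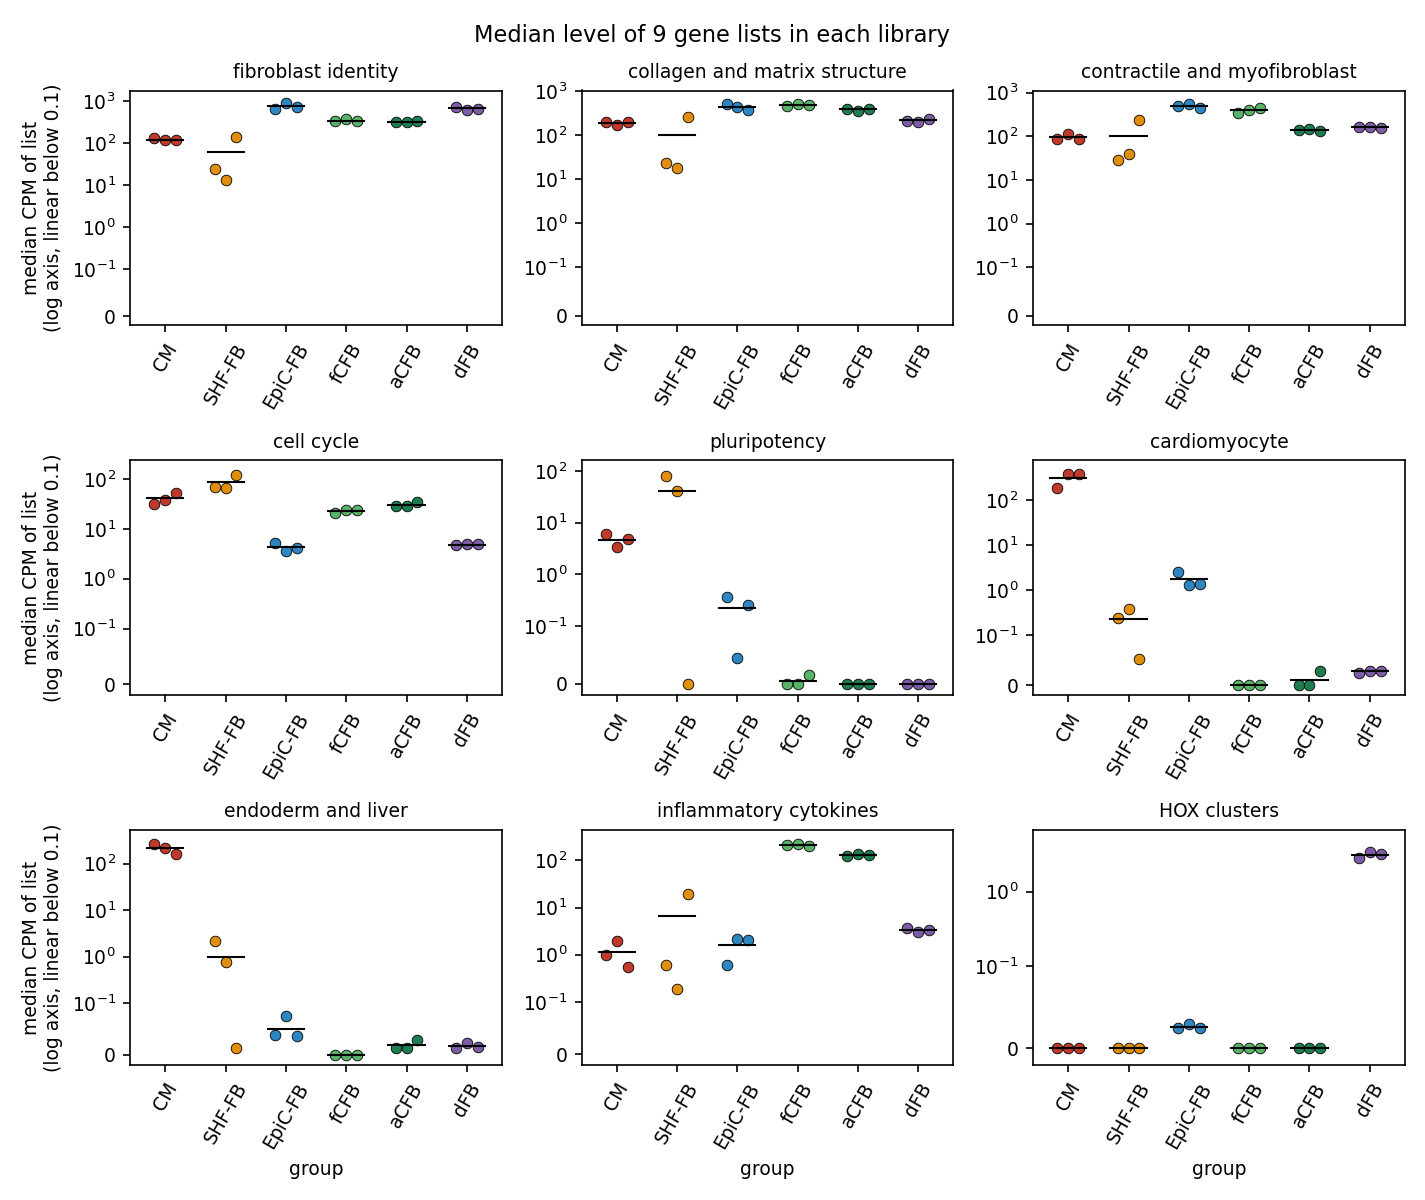
Median CPM of the members of 9 gene lists in each library; each point is 1 library, the black line is the mean of the 3 libraries of a group, and the vertical axis is logarithmic above 0.1 and linear below. SHF-FB 1 and 2 carry the highest pluripotency medians (79.9 and 40.4 CPM), and the CM libraries the highest endoderm and liver medians (158 to 265 CPM).

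The EpiC-FB against SHF-FB comparison asks how cardiac fibroblasts of the 2 developmental routes differ. CXCL12, a chemokine (Entrez 6387, chromosome 10, 44370165 to 44385097 in GRCh38), stood at 786 ± 34.8 CPM in EpiC-FB against 10.4 ± 4.8 in SHF-FB (SD, n = 3), a log2 change of 6.19 ± 0.42 (SE; adjusted p = 0.00261). IGFBP3, an insulin-like growth factor binding protein, rose by 6.79 ± 0.47 (adjusted p = 0.00267), BAMBI, a TGF-beta pseudoreceptor, by 5.60 ± 0.54 (adjusted p = 0.0053), and MYL7, the atrial myosin light chain, by 10.36 ± 0.42 (adjusted p = 0.00194). SLC7A11, a cystine transporter (Entrez 23657, chromosome 4, 138164097 to 138242349), fell by 8.58 ± 0.27 (adjusted p = 0.00117), from 451 ± 48.4 CPM in SHF-FB to 1.22 ± 0.157 in EpiC-FB. WNT7B, a WNT ligand, had no count in EpiC-FB and was at least 2280-fold lower there, against a floor of 3 counts over the group. KIAA1210 and the bile acid receptor NR1H4 had 2 counts each over the SHF-FB libraries, and their count ratios were 5530 (95% interval 1530 to 45700) and 3850 (1060 to 31800).

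All 31 tested members of the cell cycle list were lower in EpiC-FB than in SHF-FB, with a median log2 change of -4.21 (camera, adjusted p = 6.78e-27). With an estimated correlation between genes, the adjusted p was 0.376 for this list and for each other list called in this comparison. BIRC5, a mitotic survivin, changed by -5.73 ± 0.47 and MKI67, the Ki-67 proliferation antigen, by -5.89 ± 0.73, and MKI67 stood at 3.15 ± 1.87 CPM in EpiC-FB against 179 ± 93.5 in SHF-FB. Of the 21 fibroblast identity genes 7 rose and none fell, 14 were not called, and the median was 3.31 (adjusted p = 3.32e-08). DCN, the matrix proteoglycan decorin, rose by 8.41 ± 1.93 and LUM, lumican, by 8.21 ± 1.23. Of 48 collagen and matrix genes 12 rose and 36 were not called (median 2.47, adjusted p = 5.74e-11), or 15 when adjusted over the list alone. The list median was 22.7 and 18.1 CPM in SHF-FB 1 and 2 but 255 in SHF-FB 3, against 377 to 502 in EpiC-FB, and without SHF-FB 3 the median change was 4.59. Of 21 contractile genes 7 rose and 14 were not called (median 1.80, adjusted p = 3.32e-08), or 10 when adjusted over the list alone, among them ACTA2, smooth muscle actin, at 1560 ± 390 against 8.15 ± 9.24 CPM. The contractile median was 28.6, 39.2 and 239 CPM in SHF-FB 1, 2 and 3 against 451 to 562 in EpiC-FB, and without SHF-FB 3 the median change was 3.70. HOX genes (5 of 13 higher), mural cell genes (3 of 12), cardiomyocyte genes (8 of 27), TGF-beta signalling genes (7 of 22, with 1 lower) and cardiac transcription factors (4 of 20) also passed the set test upward, and glycolysis genes (7 of 19 lower) passed it downward. Median levels in SHF-FB 1, 2 and 3 were 8.17, 9.21 and 83.6 CPM for TGF-beta genes, against 96.8 to 142 in EpiC-FB. Cardiac factors had 0.627, 0.376 and 4.22 CPM, against 7.38 to 14.7. Mural genes had 1.23, 1.19 and 3.32, against 37.6 to 62.9. Cardiomyocyte genes had 0.241, 0.386 and 0.0527, against 1.31 to 2.55. Glycolysis genes had 177, 164 and 251, against 134 to 183. HOX genes at 10 CPM or more numbered 0, 0 and 4, against 4 to 6. The epicardial list (adjusted p = 0.0189) lost its upward call without SHF-FB 3 (adjusted p = 0.118), though its median rose from 1.71 to 2.62. The interferon list (adjusted p = 0.0446) lost it without SHF-FB 2 (adjusted p = 0.0629) at an unchanged median of 0.48. The pluripotency list was not called (median -3.86, adjusted p = 0.178), while its median level was 79.9, 40.4 and 0 CPM in SHF-FB 1, 2 and 3. It was called lower in EpiC-FB without SHF-FB 3 (median -6.52) or without EpiC-FB 7, 8 or 9 (median -6.30, -5.99 and -5.88).

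Among the route markers, the epicardial genes WT1 (2.96 ± 2.02, adjusted p = 0.343) and TBX18 (1.54 ± 1.95, adjusted p = 0.612) and the cardiac factors GATA4 (1.38 ± 1.67, adjusted p = 0.593) and TBX20 (1.10 ± 1.89, adjusted p = 0.713) were not called, nor was the second heart field factor ISL1 (-0.98 ± 0.72, adjusted p = 0.374), which moved to -0.15 without SHF-FB 1. COL1A1 (4.03 ± 1.91, adjusted p = 0.192), PDGFRA (0.71 ± 1.54, adjusted p = 0.775), FN1 (2.59 ± 1.53, adjusted p = 0.278) and POSTN (1.95 ± 1.86, adjusted p = 0.496) missed the threshold as well. Without SHF-FB 3, the tests called WT1 (8.83), TBX18 (7.93), GATA4 (6.19), TBX20 (5.86), COL1A1 (8.95), PDGFRA (5.01), FN1 (6.24) and POSTN (7.62) higher in EpiC-FB. Without SHF-FB 1 or SHF-FB 2 some values fell, to 0.52 and 0.55 for TBX20 and to 0.15 in both cases for PDGFRA. TBX18 fell to 0.96 in both cases, and GATA4 to 0.82 and 0.81. TCF21, a factor of epicardial fibroblast precursors, was called higher in EpiC-FB (3.98 ± 0.75, adjusted p = 0.0224) at levels of 1.34 ± 0.558 against 0.0804 ± 0.0584 CPM.

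The edgeR quasi-likelihood test called 1136 genes higher and 1252 lower in EpiC-FB among 16681, a higher share of 47.6%, and 57.9% with limma on log2(TPM + 1), which also changes the scaling, the test and the genes tested. Each single library moved the number of calls, from 2388 to 791 without SHF-FB 1, 685 without SHF-FB 2, 8442 without SHF-FB 3, and 483, 285 and 234 without EpiC-FB 7, 8 and 9. Without both SHF-FB 1 and 2, a choice made after the data were seen, 3036 genes were higher and 2282 lower, and 1907 of the 2388 calls were shared. Of the 50 called genes that the naming rule selected, 15 kept the call in every omission, and 35 lost it without EpiC-FB 9, among them DCN, LUM, ACTA2, MKI67 and TCF21. CXCL12, IGFBP3, BAMBI, MYL7, SLC7A11, WNT7B, KIAA1210, NR1H4 and BIRC5 were among the 15.

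**Figure D3:**
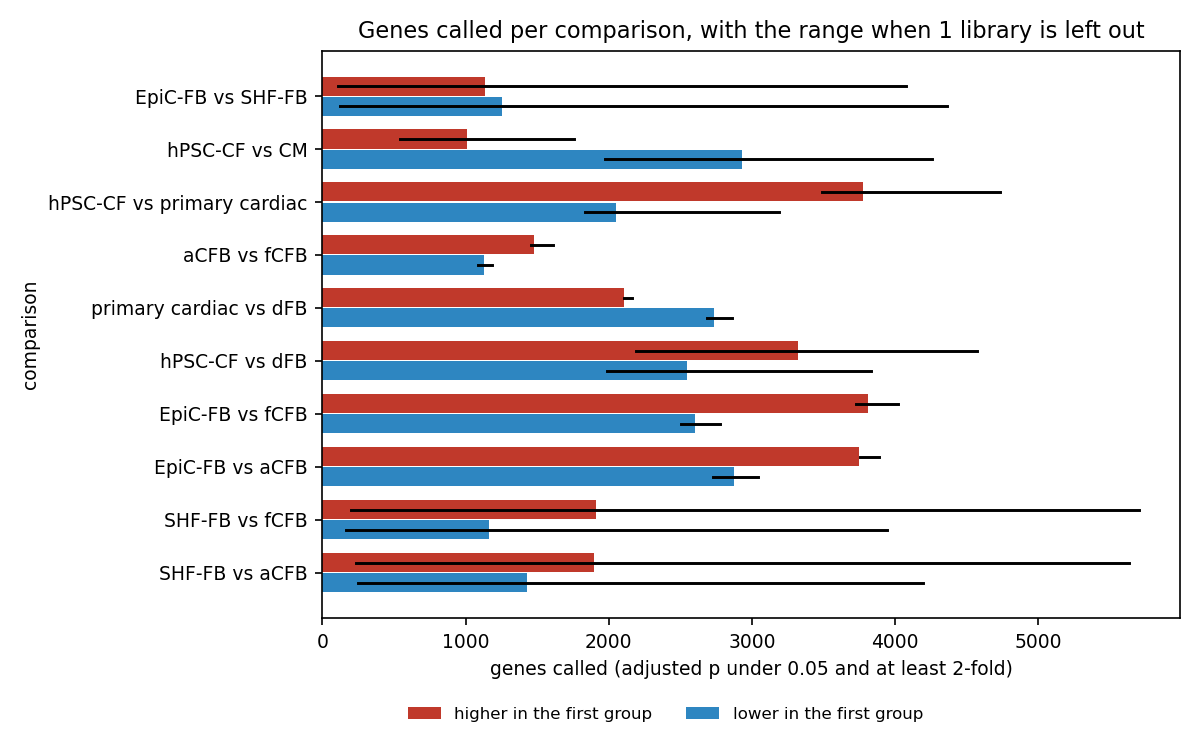
Genes called higher (red) or lower (blue) in the first group of each comparison; the horizontal axis counts genes and black lines span the lowest and highest count when 1 library is left out. The EpiC-FB against SHF-FB bars, 1136 and 1252 genes, span 109 to 4080 and 125 to 4362, and the aCFB against fCFB bars, 1480 and 1126, span 1460 to 1609 and 1090 to 1187.

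Both stem cell derived fibroblast groups, averaged with equal weight (hPSC-CF), were compared with CM. This asks how fibroblasts and cardiomyocytes differ that the labels assign to the same line. A wrong label stays open for some SHF-FB libraries and for CM 5. Of all 18 libraries, 1 differed from the rest of its group in donor-linked transcripts. All 33 cardiomyocyte genes were lower in the fibroblasts (median -8.18, or -7.66 with 1 gene at its floor of 3 counts, adjusted p = 1.5e-42; 0.116 with an estimated correlation). MYH6, the alpha myosin heavy chain (Entrez 4624, chromosome 14, 23381987 to 23408273), stood at 2570 ± 2040 CPM in CM and at 0.235 ± 0.309 and 0.0648 ± 0.0614 CPM in EpiC-FB and SHF-FB, a log2 change of -14.30 ± 1.38 (adjusted p = 0.000503). TNNT2, cardiac troponin T, changed by -10.16 ± 0.81 (adjusted p = 0.000245), the cardiac factor NKX2-5 by -5.86 ± 0.57 (adjusted p = 0.000528) and the muscle methyltransferase SMYD1 by -14.23 ± 0.84 (adjusted p = 7.68e-05). On the fibroblast side THY1, a surface glycoprotein of fibroblasts, rose by 3.52 ± 0.52 (adjusted p = 0.0025), and FAP, a fibroblast activation protease, by 9.29 ± 2.33 (adjusted p = 0.0205), a call that ended without any 1 of the 3 CM libraries. GREM1, a BMP antagonist, had no count in CM and was at least 1790-fold higher in the fibroblasts. MMP16, a membrane metalloproteinase, rose by 4.05 ± 0.70 (adjusted p = 0.00459). COL1A1 (1.58 ± 1.37, adjusted p = 0.417), COL3A1 (0.72 ± 1.39, adjusted p = 0.728), FN1 (2.19 ± 1.19, adjusted p = 0.201), POSTN (1.66 ± 1.45, adjusted p = 0.423) and ACTA2 (0.31 ± 0.72, adjusted p = 0.779) were not called, and COL1A1, COL3A1 and POSTN took values of -0.76, -2.09 and -1.05 without SHF-FB 3, the last 2 of them called lower. FN1 moved to 0.48 without SHF-FB 3, and ACTA2 to -0.39 without SHF-FB 3, -0.04 and 0.06 without CM 4 or CM 5, and 1.16 without CM 6.

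Beyond muscle genes, all 12 endoderm and liver genes were lower in the fibroblasts than in CM (median -9.0, adjusted p = 1.32e-09; 0.36 with an estimated correlation). AFP, the fetal liver protein alpha-fetoprotein, stood at 4670 ± 2160 CPM in CM and changed by -10.79 ± 1.36, and FGB, a fibrinogen chain, by -10.90 ± 1.36. Of 19 glycolysis genes 14 fell (median -1.80, adjusted p = 9.35e-11; 0.116 with an estimated correlation), with PDK1, a pyruvate dehydrogenase kinase, at -3.73 ± 0.38. Cardiac transcription factors (13 of 22 lower), epithelial genes (8 of 15), epicardial genes (10 of 22) and oxidative phosphorylation genes (6 of 19) passed the set test downward too. The epicardial median in CM was highest in CM 5 (58.9 CPM, against 12.2 and 10.8 in CM 4 and CM 6), and without CM 5 the median change moved from -2.58 to -1.53, still called. TCF21 was lower in the fibroblasts (-5.76 ± 0.77, adjusted p = 0.00168), and CM 5 held 41.5 CPM against 5.892 and 6.27 in CM 4 and CM 6. Fibroblast identity genes passed upward with a median of 0.72 (4 of 21 higher, 2 lower, adjusted p = 0.0438), a call lost without SHF-FB 3, where the median was -0.03 (adjusted p = 0.593), and without CM 4 or CM 6, where it stayed at 0.82 and 0.61 (adjusted p = 0.0634 and 0.119). No list was called here with an estimated correlation, with adjusted p = 0.36 for epicardium, 0.222 for cardiac factors, 0.378 for epithelium and 0.79 for oxidative phosphorylation and fibroblast identity. The test called 1011 genes higher and 2929 lower among 18484. The higher count was 1757 without SHF-FB 3, 541 without CM 4 and 673 without CM 5, and it was 2547 with EpiC-FB alone. Without both SHF-FB 1 and 2 the counts were 2219 and 5477.

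The comparison of hPSC-CF with primary cardiac fibroblasts, the equal-weight mean of fCFB and aCFB, asks how far the stem cell derived cells differ from cells of the heart. Inflammatory, interferon and antigen presentation genes were lower in hPSC-CF than in primary cardiac fibroblasts. By one label, passage differed together with cell source (1 against 3 to 5), and the design cannot tell them apart. Of 26 inflammatory cytokine genes 23 fell and 1 rose (median -5.31, adjusted p = 5.9e-12; 0.484 with an estimated correlation). SHF-FB 3 stood apart, with an inflammatory median of 19 CPM against 0.188 to 2.2 CPM in the 5 other hPSC-CF libraries and 125 to 220 CPM in primary cardiac libraries. The dFB libraries held 3.05 to 3.7 CPM. For hPSC-CF against dFB the inflammatory list was not called (camera, median -0.91, adjusted p = 0.1). Without SHF-FB 3 it was called lower than in dFB (median -1.76, adjusted p = 0.00234). CSF3, a granulocyte growth factor (Entrez 1440, chromosome 17, 40015440 to 40017813), stood at 426 ± 72.1 CPM in fCFB and 229 ± 28.1 in aCFB, against 0 in EpiC-FB and 0.0176 ± 0.0304 in SHF-FB (log2 change -15.81 ± 0.65, adjusted p = 8.95e-07). CXCL6, a neutrophil chemokine, changed by -9.03 ± 1.36 (adjusted p = 0.000402) and IL6 by -4.39 ± 0.87 (adjusted p = 0.00209). Of 23 interferon response genes 15 fell and 4 rose (median -2.03, adjusted p = 3.81e-07; 0.0329 with an estimated correlation), including OAS2, an antiviral oligoadenylate synthetase (-8.04 ± 0.36). Of 12 antigen presentation genes 11 fell (median -2.98, adjusted p = 3.38e-06; 0.484 with an estimated correlation; list medians of 2.43, 1.69 and 21.7 CPM in SHF-FB 1, 2 and 3), including HLA-B (-4.17 ± 0.14), whose reads can be shared with its close paralogs.

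Of 28 cardiomyocyte genes 24 were higher in hPSC-CF than in primary cardiac fibroblasts (median 5.66, or 5.31 with 12 genes at the floor, adjusted p = 4.22e-06; 0.484 with an estimated correlation). By route, the list was called in EpiC-FB against fCFB and aCFB (median 6.69 and 6.36 over 25 tested genes, or 6.21 and 6.18 with 13 and 11 genes at the floor; adjusted p = 0.314 and 0.285 with an estimated correlation) and not called in SHF-FB (1.07 and 0.45 over 11, adjusted p = 0.298 and 0.532). The direct comparison of the routes gave a median of 1.73 over 27 genes (adjusted p = 5.53e-05; 0.376 with an estimated correlation). MYL7 was at 226 ± 27.8 CPM in EpiC-FB and 0.165 ± 0.0663 in SHF-FB, and had 1 count over the 6 primary cardiac libraries. Pluripotency genes (9 of 10 higher, median 8.29, or 7.96 with 4 genes at the floor, adjusted p = 0.00884; 0.714 with an estimated correlation) were higher too, and without both SHF-FB 1 and 2 the median was 4.32 (adjusted p = 0.0842). In EpiC-FB the pluripotency median was 7.84 against fCFB and 6.58 against aCFB, or 5.92 and 5.34 with 3 genes at the floor in each. The levels behind these values were low. The list median was 0.0452 to 0.361 CPM in the EpiC-FB libraries and 0 to 0.0143 CPM in the primary cardiac libraries. DPPA4 stood at 89.5 ± 80.1 CPM in SHF-FB and 8.88 ± 2.09 in EpiC-FB. SOX11, a factor of embryonic progenitors, rose by 11.88 ± 0.53 (adjusted p = 1.3e-06), MEST, an imprinted gene, by 7.75 ± 0.54 (adjusted p = 2.91e-06), and THY1 by 4.79 ± 0.35 (adjusted p = 3.86e-06). TCF21 was lower in hPSC-CF (-6.92 ± 0.33, adjusted p = 2.88e-07), with 20.2 ± 0.861 CPM in fCFB and 83.2 ± 3.62 in aCFB. The laminin gene LAMA2 fell by 5.08 ± 0.47 (adjusted p = 1.75e-05) and the protease CTSK by 3.26 ± 0.12 (adjusted p = 5.38e-08).

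Several genes were transcribed in every primary cardiac library and close to silent in hPSC-CF. CAT, the peroxide-degrading enzyme catalase (Entrez 847, chromosome 11, 34438934 to 34472060), stood at 49.2 ± 0.478 CPM in fCFB, 91.5 ± 3.8 in aCFB and 98.6 ± 3.58 in dFB, had no count in any of the 6 hPSC-CF libraries, and was at least 11600-fold lower there than in primary cardiac fibroblasts. FPR1, a formyl peptide receptor, was at least 4540-fold lower. MEG3, an imprinted non-coding RNA, changed by -12.28 ± 1.26 (adjusted p = 0.000118) and TYW3, a tRNA-modifying enzyme, by -11.18 ± 0.79 (adjusted p = 1.52e-05).

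Of the marker genes, GATA4 (0.51 ± 0.88, adjusted p = 0.64), HAND2 (0.70 ± 1.12, adjusted p = 0.618), PDGFRB (0.36 ± 0.61, adjusted p = 0.641), COL1A1 (0.52 ± 0.91, adjusted p = 0.65) and COL3A1 (-0.60 ± 1.00, adjusted p = 0.632) were not called between hPSC-CF and primary cardiac fibroblasts. TBX20 (-1.65) and PDGFRA (-1.53) were not called either, and moved to -3.97 and -3.64 without SHF-FB 3. POSTN, the matricellular protein periostin, was lower (-3.07 ± 1.05, adjusted p = 0.0305) and ACTA2 higher (1.26 ± 0.44, adjusted p = 0.0342). The POSTN call was lost without any 1 of the EpiC-FB, fCFB or aCFB libraries, and the ACTA2 call without any 1 of these or SHF-FB 3. Without SHF-FB 3 the tests called GATA4 (-1.85), HAND2 (-3.34), COL1A1 (-1.90) and COL3A1 (-3.49) lower in hPSC-CF, and PDGFRB moved to -0.94, POSTN to -5.86 and ACTA2 to 0.48. The test called 3775 genes higher and 2054 lower among 17515, and 3190 were lower without SHF-FB 3. Without both SHF-FB 1 and 2 the higher share of calls was 51.9% instead of 64.8%.

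The aCFB against fCFB comparison asks how adult and fetal cardiac fibroblasts differ in these cultures. Of 23 interferon genes 14 rose and none fell in aCFB (median 1.59, adjusted p = 5.39e-12; 0.245 with an estimated correlation), with IFI44L at 134 ± 5.91 CPM in aCFB and 7.54 ± 0.876 in fCFB (log2 change 4.16 ± 0.09, adjusted p = 1.24e-14). Of 20 contractile genes 9 fell and none rose (median -0.83, adjusted p = 7.95e-12; 0.245 with an estimated correlation), with TAGLN, the actin-binding protein transgelin, at -2.12 ± 0.08 (adjusted p = 1.4e-11). Inflammatory genes split: 6 rose and 11 fell of 26 (median -0.85, adjusted p = 8.37e-05; 0.314 with an estimated correlation). The alarmin IL33 rose by 5.52 ± 0.10 and its receptor IL1RL1 by 5.28 ± 0.10, while IL1B fell by 4.11 ± 0.07, CSF2 fell by 5.44 ± 0.17 and IL6 fell by 2.04 ± 0.07.

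The collagen and matrix list did not pass between aCFB and fCFB (9 higher and 8 lower of 48, median 0.01, adjusted p = 0.806), and its members moved both ways. COL4A4, a basement membrane collagen, rose by 8.91 ± 0.11 (adjusted p = 6.17e-17), from 0.304 ± 0.0399 to 144 ± 6.37 CPM, and LAMA2 by 2.82 ± 0.10, while TNC, tenascin C, changed by -4.09 ± 0.14 and MMP1, a collagenase, by -2.98 ± 0.09. TIMP1, a metalloproteinase inhibitor, rose by 2.91 ± 0.09 and TIMP3 fell by 2.85 ± 0.09. ADH1B, an alcohol dehydrogenase (Entrez 125, chromosome 4, 99304971 to 99321401), rose by 9.85 ± 0.22 (adjusted p = 2.47e-12), and KIT, a receptor tyrosine kinase, changed by -7.59 ± 0.15 (adjusted p = 5.93e-14). CBSL had 3 counts in aCFB and 8.44 CPM in fCFB, a count ratio of 630 (95% interval 216 to 3050), but its sequence nearly matches CBS, so its reads are uncertain. TCF21 (2.06 ± 0.07, adjusted p = 1.32e-12) and PDGFRA (1.43 ± 0.08, adjusted p = 4.81e-10) rose in aCFB, and COL1A1, POSTN and MKI67 were not called (0.38 ± 0.21, -0.14 ± 0.11 and 0.23 ± 0.15, adjusted p = 0.173, 0.296 and 0.251). These small values moved with single libraries, COL1A1 to 0.18 without fCFB 10 and 0.61 without fCFB 12, POSTN to -0.23, -0.01 and -0.07 without fCFB 10, fCFB 11 and aCFB 14, and MKI67 to 0.14, 0.34 and 0.06 without fCFB 10, aCFB 14 and aCFB 15. GATA4 (0.65 ± 0.08) and TBX20 (0.84 ± 0.11) passed the p threshold but stayed under the 2-fold minimum. The test called 1480 genes higher and 1126 lower among 15298. When all 18 libraries shared 1 estimate of spread the counts were 845 and 628, and with limma on log2(TPM + 1) 692 and 526.

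Primary cardiac fibroblasts (fCFB and aCFB) were set against dFB to ask what separates heart from skin fibroblasts. Heart cells held more inflammatory and endothelial transcript and skin cells more HOX transcript. Of 26 inflammatory genes 22 were higher in the cardiac cells and none lower (median 4.70, adjusted p = 8.55e-54; 0.0016 with an estimated correlation). CSF3 rose by 10.75 ± 0.22 (adjusted p = 1.09e-12), CXCL6 by 10.25 ± 0.18 (adjusted p = 2.55e-15) and IL1B by 9.74 ± 0.12 (adjusted p = 1.69e-18). Of 29 HOX genes 28 were lower in cardiac cells (median -7.89, or -7.22 with 7 genes at the floor, adjusted p = 1.79e-30; 0.00201 with an estimated correlation). HOXC10 (Entrez 3226, chromosome 12, 53985146 to 53990279) stood at 64.5 ± 4.46 CPM in dFB, 0 in fCFB and 0.0283 ± 0.0293 in aCFB, and HOXB9 changed by -10.50 ± 0.24 (adjusted p = 9.51e-15). Of 16 endothelial and endocardial genes 15 were higher in cardiac cells (median 3.88, adjusted p = 6.02e-26; 0.00781 with an estimated correlation). CDH5, the endothelial cadherin, stood at 250 ± 26.6 CPM in fCFB and 82.1 ± 2.85 in aCFB and had no count in dFB, a difference of at least 11700-fold.

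Cell cycle genes were higher in primary cardiac than in dermal cells (25 of 31, median 2.30, adjusted p = 4.19e-14; 0.213 with an estimated correlation), with MKI67 at 3.63 ± 0.17 (adjusted p = 5.14e-09). Dermal and limb mesenchyme genes were lower (10 of 11, with 1 higher, median -2.73, adjusted p = 4.3e-06; 0.0186 with an estimated correlation), among them TWIST2 (-3.25 ± 0.07) and TBX15 (-2.73 ± 0.07). Epicardial genes passed upward (7 higher and 4 lower of 14, adjusted p = 0.00014; 0.0265 with an estimated correlation), including TCF21 (6.14 ± 0.09). GATA4 had no count in dFB and was at least 2910-fold higher in the cardiac cells, and TBX20 (4.29 ± 0.15) and GATA6 (4.24 ± 0.27) were higher too. WT1 had 2 counts over the dFB libraries, and its count ratio was 1790 (95% interval 496 to 14800). TBX5, a factor of heart and forelimb, was higher in dFB (-1.92 ± 0.14), and HAND2 (-0.76 ± 0.08) and ACTA2 (-0.18 ± 0.05) stayed under the 2-fold minimum. POSTN was 7.47 ± 0.14 higher on the log2 scale and COL1A1 was not called (0.23 ± 0.18, adjusted p = 0.281; 0.12, 0.14 and 0.37 without fCFB 12, dFB 16 and dFB 18). The epithelial list had a median of -1.05 yet passed the set test upward (adjusted p = 0.00563; 0.238 with an estimated correlation), with KRT7 at 6.49 ± 0.11 and KRT18 at 5.27 ± 0.10. EMX2OS fell by 10.35 ± 0.18, but it is antisense to its neighbour and the strand setting of the counting is not given, so its reads are uncertain. The test called 2106 genes higher and 2738 lower among 16216, a higher share of 43.5%, against 58.5% with limma on log2(TPM + 1).

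The hPSC-CF against dFB comparison sets the stem cell derived cardiac fibroblasts against skin fibroblasts. HOX genes were lower (22 of 29, median -6.37, or -6.34 with 8 genes at the floor, adjusted p = 5.49e-16) and so were interferon genes (17 of 23, median -3.08, adjusted p = 4.66e-09). Cell cycle genes were higher (27 of 31, median 2.17, adjusted p = 1.46e-10), but with EpiC-FB alone the median was -0.09 (adjusted p = 0.878). With an estimated correlation the adjusted p was 0.361, 0.361 and 0.451 for these lists. GATA4 was at least 4270-fold higher in hPSC-CF and GATA6 rose by 5.62 ± 0.96 (adjusted p = 0.00255). GPC3, a glypican (Entrez 2719, chromosome X, 133535745 to 133985594), rose by 12.59 ± 2.60 (adjusted p = 0.00587) and KRT8, a keratin of simple epithelia, by 7.80 ± 0.44 (adjusted p = 2.17e-05). APOD, a lipid carrier, changed by -11.76 ± 0.93 (adjusted p = 7.39e-05), CTSK by -7.04 ± 0.18 (adjusted p = 1.5e-06), and CAT was at least 15900-fold lower. TBX20, TBX5, HAND2, TCF21, PRRX1, COL1A1, POSTN and ACTA2 were not called, with adjusted p from 0.0653 for POSTN to 0.997 for HAND2. Without SHF-FB 3, TBX5 (-4.05), HAND2 (-4.10), PRRX1 (-4.25) and COL1A1 (-1.66) were called lower and POSTN (1.62) higher in hPSC-CF, and POSTN was also called without SHF-FB 1 (4.71) or SHF-FB 2 (4.75). TBX20 moved to 0.32 and ACTA2 to 0.31 without SHF-FB 3, not called. The test called 3323 genes higher and 2545 lower among 17502, a higher share of 56.6%, against 73.6% with limma on log2(TPM + 1). The lower count was 3833 without SHF-FB 3 and the higher count 2189 without dFB 17.

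Each stem cell derived group was then compared with each primary cardiac group. EpiC-FB differed in 3812 genes higher and 2603 lower from fCFB, and in 3752 and 2873 from aCFB. SHF-FB differed in 1912 and 1165 genes from fCFB, and in 1898 and 1430 from aCFB. The SHF-FB against fCFB calls, 3077 in all, numbered 1385, 1330 and 9649 without SHF-FB 1, 2 and 3, and 403, 365 and 424 without fCFB 10, 11 and 12. The SHF-FB against aCFB calls, 3328 in all, numbered 1781, 1707 and 9835 without SHF-FB 1, 2 and 3, and 487, 520 and 546 without aCFB 13, 14 and 15. Inflammatory genes were lower in EpiC-FB than in fCFB (20 of 25, adjusted p = 2.24e-30; 0.0438 with an estimated correlation) and aCFB (22 of 26, adjusted p = 7.5e-22; 0.0387 with an estimated correlation).

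Gene sets taken from the primary libraries were tested in EpiC-FB against SHF-FB, which share no library with them. The genes higher in aCFB than fCFB were higher in EpiC-FB (median 0.53, 38 called higher and 11 lower of 184, adjusted p = 0.000483), as were genes higher in dFB than in cardiac cells (median 0.62, 35 higher and 13 lower of 180, adjusted p = 0.000309). Neither call held with an estimated correlation (adjusted p = 0.41 for both), and the adult set missed the threshold at a size of 100 genes (adjusted p = 0.189). These sets were tested with all libraries only. How far the calls rest on SHF-FB 1 and 2 was not tested. The fetal and cardiac sets were not called (median -0.28 and -0.12, adjusted p = 0.665 for both). The root mean square distance of log2 CPM to aCFB minus that to fCFB was -0.01 ± 0.02 in EpiC-FB and 0.02 ± 0.13 in SHF-FB (SD, n = 3). An exact permutation test, two-sided, gave p = 1, where the smallest possible p is 0.1. The SHF-FB libraries differed among themselves in this measure, with -0.06 in both SHF-FB 1 and SHF-FB 2 and 0.17 in SHF-FB 3.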

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

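The tests of depth, swap and mixture for SHF-FB, the test of genes off in SHF-FB 3 but on in every primary library, and both tests for CM 5 were chosen only after the result was seen. The test of the share of fCFB genes, the counts of other splits and the comparisons between routes were chosen before.

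Both H9 fibroblast routes were compared with the same primary group, and 3 gene lists moved in opposite directions. Fibroblast identity genes had a median log2 change against fCFB of 1.16 in EpiC-FB (adjusted p = 0.0378) and -1.54 in SHF-FB (adjusted p = 0.00245), and the direct comparison of the routes gave 3.31 (adjusted p = 3.32e-08). Contractile genes had 0.72 in EpiC-FB (adjusted p = 0.000536) and -1.14 in SHF-FB (adjusted p = 0.00388), with 1.80 between the routes (adjusted p = 3.32e-08). Cell cycle genes had -2.08 (adjusted p = 1.77e-05) and 2.07 (adjusted p = 2.02e-15) against fCFB, and -2.35 (adjusted p = 1.39e-08) and 1.63 (adjusted p = 7.74e-12) against aCFB. Between the routes they had -4.21 (adjusted p = 6.78e-27). With an estimated correlation between genes, the adjusted p of all 3 lists between the routes was 0.376. The groups hold 3 libraries each, so no single library was tested as an outlier within its group.

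The cell cycle difference held in every SHF-FB library, with list medians of 69, 67 and 118 CPM against 5.15, 3.56 and 4.07 CPM in EpiC-FB. The fibroblast identity and contractile differences rest on SHF-FB 1 and 2 more than on SHF-FB 3, with medians of 24.2, 13.1 and 145 CPM and of 28.6, 39.2 and 239 CPM in SHF-FB 1, 2 and 3. Growth state at harvest and lineage are both open explanations of the cell cycle difference and were not tested apart, since the labels give no measure of growth. Another cell state or a wrong label is open too for SHF-FB 1 and 2, whose pluripotency medians were 79.9 and 40.4 CPM. SHF-FB 3, with a pluripotency median of 0 CPM, had the highest cell cycle median.

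SHF-FB 1 and 2 stood apart from SHF-FB 3, and technical causes were weighed first. Lower depth is argued against, since SHF-FB 1 and 2 held at least 17380 genes with 10 or more counts and SHF-FB 3 held 15032. Total counts were 62535314, 74901335 and 76456319 in SHF-FB 1, 2 and 3. The number of genes cannot decide on poorer RNA, since it also differed between cell types (17711 in CM 5, 14685 in fCFB 11). A swap with a library of another group would leave a partner out of place, and 0 of the 15 libraries of the other groups lay closest to a library outside their group. Cells mostly like those of SHF-FB 3, with others mixed in, would keep at least 50% of the level of its fibroblast and matrix genes. The median over 41 such genes was 7.04% in SHF-FB 1 (quartiles 3.62% and 28.5%) and 7.47% in SHF-FB 2 (quartiles 2.44% and 27%), which argues against that mixture. A wrong label with no partner in the series, a small share of such cells, and differentiations that ended in another cell state stay open. Poorer RNA stays open as well. Levels of LIN28A, SOX2 and OTX2 could come from cells that kept or regained a progenitor state, a candidate explanation that no test here separates from a wrong label.

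SHF-FB 3 lay closest to fCFB. The correlations with fCFB decide nothing, as those libraries are technical replicates. A library made from the fCFB cells is argued against by 12 genes chosen without SHF-FB 3, each at 10 CPM or more in every primary library and at most 0.5 CPM in the 5 other hPSC-CF libraries. In SHF-FB 3, 9 of the 12 were at most 0.5 CPM and 0 reached 10 CPM; CAT and TYW3 among them had been seen before the test was set. RNA at the levels of these fCFB libraries making up most of SHF-FB 3 is argued against too. Of 1938 genes at 100 CPM or more in every fCFB library, 6.81% lay below 25% of the fCFB mean in SHF-FB 3. The bound of 5% was written before the result was seen. Since the fCFB libraries are technical replicates, the percentage that a separate culture of fCFB cells would give is unknown. For such a culture the percentage decides nothing. This percentage and the medians over 41 genes were first computed on CPM without TMM scaling and recomputed with it after they had been seen; no bound was crossed by that change. The percentage below that level was 2.06% in aCFB 13, 7.33% in dFB 16, 10.2% in EpiC-FB 8 and 26.7% in SHF-FB 1. That differentiation of second heart field cells reached a state near fetal cardiac fibroblasts is a biological hypothesis the design allows. Another primary or differentiated fibroblast under this label stays open as well.

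CM 5 held CAT at 79.8% and TYW3 at 63.6% of the aCFB mean, while CM 4 and CM 6 held CAT at 0.069 and 0.022 CPM and TYW3 at 0.735 and 1.30 CPM. These genes and MEG3 were chosen here after their values were seen. Primary fibroblast RNA in CM 5 is argued against, since MEG3 stood at 0.0585% of the aCFB mean. In CM 5, 8 genes were at 10 CPM or more while CM 4 and CM 6 had at most 0.5 CPM, and 0 genes were on in this way in CM 4 or in CM 6. The 8 genes were CAT, FRG1CP, ZNF667, NPHS1, CCDC68, FRG1BP, THNSL2 and ZNF667-AS1, and CAT had defined the pattern. Cells of another origin under the CM 5 label would need such genes, so this explanation may hold, but the condition for it was settled after the 8 genes had been seen. A different outcome of that differentiation, another make-up of that culture or a wrong label stay open.

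The number of genes called was compared with other splits of the same libraries. For hPSC-CF against CM, 1 of 50 splits, the real one, called as many genes (3940, highest other 1090), and for hPSC-CF against primary cardiac 1 of 50 (5829, highest other 2857). For primary cardiac against dFB it was 1 of 50 (4844, highest other 4100) and for hPSC-CF against dFB 1 of 50 (5868, highest other 3758). For hPSC-CF against CM, which per the labels holds independent differentiations alone, 1 of 50 is the smallest share these splits could give. Most other splits put unlike cell types into one group, which raises the spread within it, so the real split was likely to rank first. The share therefore cannot decide on chance as the source of the count. The split with 1090 calls set CM and EpiC-FB against SHF-FB. The splits take the labels as given, and a wrong label stays open for some SHF-FB and CM libraries. The primary libraries are technical replicates, so splits that exchange them measure technical spread and say nothing of chance differences between cultures or donors. For primary cardiac against dFB nothing further follows from them. The highest other splits of the last 2 comparisons kept all dFB libraries together and mixed libraries within the other side, so they point to the same structure of the samples. Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05, and 1 of 10, the real one, called as many. The real counts were 2388 for EpiC-FB against SHF-FB, 2606 for aCFB against fCFB, 6415 and 6625 for EpiC-FB against fCFB and aCFB, and 3077 and 3328 for SHF-FB against fCFB and aCFB, with 0 as the highest other in each.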

How the results depend on the processing

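Omitting SHF-FB 1 and 2 together and using EpiC-FB alone were tests chosen only after the result was seen; the other alternatives were planned. No paired analysis was possible because replicate numbers do not recur between groups. For the moved and reversed values below, the cause was not tested.

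Leaving out 1 library in turn, genes called higher and lower ranged from 109 to 4080 and 125 to 4362 for EpiC-FB against SHF-FB (1136 and 1252 with all libraries), from 202 to 5704 and 163 to 3945 for SHF-FB against fCFB, and from 236 to 5637 and 251 to 4198 for SHF-FB against aCFB. The highest counts came without SHF-FB 3. Genes higher ranged from 541 to 1757 for hPSC-CF against CM (1011) and from 2189 to 4575 for hPSC-CF against dFB (3323), and genes lower from 1838 to 3190 for hPSC-CF against primary cardiac (2054) and from 1988 to 3833 for hPSC-CF against dFB (2545). Called lists ranged from 2 to 10 lower for EpiC-FB against SHF-FB (2), 0 to 4 higher for hPSC-CF against CM (2), 3 to 5 higher for aCFB against fCFB (5) and 5 to 10 lower for hPSC-CF against dFB (5). For aCFB against fCFB and primary cardiac against dFB the gene counts stayed within 1460 to 1609 and 1090 to 1187, and 2104 to 2163 and 2684 to 2864.

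The DESeq2 Wald test called 2038 genes higher and 2243 lower for EpiC-FB against SHF-FB, 1534 higher for hPSC-CF against CM and 1813 lower for SHF-FB against fCFB. With all 18 libraries in one fit the counts were 2653 and 3193 for EpiC-FB against SHF-FB, 1640 higher for hPSC-CF against CM, and 845 and 628 for aCFB against fCFB. Without a fold minimum they were 1933 higher for hPSC-CF against CM, 4091 lower for hPSC-CF against primary cardiac, 4079 and 3952 for aCFB against fCFB, and 5454 and 6114 for primary cardiac against dFB, where dropping a condition can only add calls. With limma on log2(TPM + 1), which changes the values, scaling, test and genes tested together, they were 1227 lower for hPSC-CF against primary cardiac, 692 and 526 for aCFB against fCFB, 1064 lower for primary cardiac against dFB and 1253 lower for hPSC-CF against dFB. The median of all genes under that setting was 0.33 for hPSC-CF against primary cardiac (0.08 in the chosen analysis), 0.13 for primary cardiac against dFB (-0.03) and 0.47 for hPSC-CF against dFB (0.09). Higher calls took 57.9% of calls under it for EpiC-FB against SHF-FB (47.6%), 58.5% for primary cardiac against dFB (43.5%) and 73.6% for hPSC-CF against dFB (56.6%), and 36.5% without a fold minimum for hPSC-CF against CM (25.7%).

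With an estimated correlation the lists called higher and lower were 0 and 0 for EpiC-FB against SHF-FB (11 and 2), 0 and 0 for hPSC-CF against CM (2 and 10), 0 and 1 for hPSC-CF against primary cardiac (7 and 7), 0 and 0 for aCFB against fCFB (5 and 7), 3 and 2 for primary cardiac against dFB (7 and 5) and 0 and 0 for hPSC-CF against dFB (7 and 5). The fry test called 0 higher for hPSC-CF against CM, 12 higher for aCFB against fCFB, 16 and 10 for primary cardiac against dFB and 8 lower for hPSC-CF against dFB. DESeq2 size factors gave 1 list higher for hPSC-CF against CM. With all 18 libraries it was 1 higher there, 2 and 2 for aCFB against fCFB and 3 lower for primary cardiac against dFB.

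Without SHF-FB 1 and 2, genes called were 3036 higher and 2282 lower for EpiC-FB against SHF-FB, 2219 and 5477 for hPSC-CF against CM, and 2280 and 2927 lower for SHF-FB against fCFB and aCFB. Lists were 6 and 5 for EpiC-FB against SHF-FB, 10 higher for hPSC-CF against CM, and 4 and 3 for hPSC-CF against primary cardiac. EpiC-FB alone gave 2547 genes and 7 lists higher against CM.

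Directions reversed as follows, among results called with all libraries or in the changed setting. The direction of a list is that of its set test and can differ from the sign of its median. For EpiC-FB against SHF-FB, inflammatory genes leaned upward, not called, with a median of -0.61 (adjusted p = 0.779). They were called downward without SHF-FB 1 and 2 (-2.45) and upward without SHF-FB 3 (3.21, adjusted p = 0.0148). Without SHF-FB 1 and 2, senescence genes had 0.49 for hPSC-CF against CM, or 1.19 with EpiC-FB alone. Without SHF-FB 3, COL3A1 had -2.09 and POSTN -1.05 against CM (highest 1.01 and 2.04 without 1 other library). Against primary cardiac, GATA4 had -1.85, HAND2 -3.34 and COL1A1 -1.90 (highest 0.78, 0.98 and 0.79), and COL1A1 had -1.66 against dFB (highest 1.09). With EpiC-FB alone, COL3A1 had 2.05, collagen and matrix genes 1.29 and matrix remodelling genes 0.22 against primary cardiac. Against dFB, TCF21 had 1.21, fibroblast identity genes 0.17 and collagen and matrix genes 1.24.

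The adult signature (0.53) and the dermal signature (0.62) lost the call with an estimated correlation (adjusted p = 0.41 for both), with the same medians, and the adult one at 100 genes (0.27, adjusted p = 0.189). The EpiC-FB distance to aCFB minus that to fCFB was -0.0131, and 0.00563 with a prior count of 10, 0.012 on log2(TPM + 1) and -0.0573 over the 2000 most variable genes.

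Over the planned settings, 6459 single-gene values kept their side of the threshold, 351 lost and 44 gained a call, and 6 reversed. For the set tests of lists these were 2032, 119, 105 and 0. Only a result called in at least 1 of the settings compared could count as reversed. Results called in neither count as kept even where the sign changed, as for ACTA2 against CM (0.31 to -0.39 without SHF-FB 3). The median of a list changed sign in 95 cases, of which 3 were called on one side and 0 on both. These 3, each without SHF-FB 3, were inflammatory genes above, fibroblast identity for hPSC-CF against CM (0.72 to -0.03) and matrix remodelling for hPSC-CF against dFB (0.17 to -1.56). Depth limits the test of genes near the count minimum of 10; lower depth was not simulated.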

Other observations

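The choice of DIRAS3, of the endoderm counts and of WT1, TBX18 and CAT in CM, came only after the result was seen. They are values without a test.

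Endoderm and liver transcripts were abundant in every CM library. Of 12 list members 9 stood at 10 CPM or more in each of the 3 CM libraries, and 0 had a library of another group above the lowest CM library. AFP stood at 4392, 6943 and 2658 CPM in CM 4, 5 and 6.

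CM 5 also held the most transcript of the epicardial genes WT1 and TBX18 among CM. WT1 stood at 57.07 CPM against 9.15 and 5.70, and TBX18 at 205.9 against 49.6 and 71.4, in CM 4 and CM 6. Apart from the epicardial genes, CAT stood at 73.0 CPM in CM 5 against 0.069 and 0.022 in CM 4 and CM 6. DIRAS3 stood at 252 CPM in SHF-FB 3 and at 0.941 and 1.05 CPM in SHF-FB 1 and 2, beside 58.7, 55.9 and 81.3 CPM in CM 4, 5 and 6.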
